A study of Mus musculus with 20 samples.

How the data were processed

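RNA was measured in 20 mouse libraries, labelled as liver at week 24, with 5 in each of 4 groups that cross genotype (WT or labelled LXRα-/-) with diet (chow or HFD). Groups and replicate numbers were taken from the sample titles. Libraries were made from poly(A)-selected RNA and sequenced in pairs on an Illumina instrument, per the labels' protocols. The same protocol text speaks of RNA of an adipose type, against the tissue label. The labels give neither the animal behind each library nor a shared batch or litter, so p-values measure the spread between these libraries.

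The deposited table gives whole-number counts per gene for each library, and FPKM (fragments scaled to gene length and library size) beside them, per the file headers. The submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 and the build mm8, with no role or order. The program that made the counts, its rule for reads that fit several genes and its strand setting are not given in the sources used here. Counts of paralogs, pseudogenes and overlapping or antisense genes are therefore uncertain. Of 55385 gene IDs, 55144 were in the GENCODE M21 annotation of GRCm38, where 99.6% had the same start and 94.4% the same end. Coordinates are printed as the file gives them, and they match GRCm38, and an mm8 annotation was not used here. Within a gene the deposited FPKM values were proportional to the counts, with a median coefficient of variation of 0.077% across libraries, and the 705798 counts of 0 were listed at an FPKM of 0.0001.

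The test fixed before the data were examined assumed FPKM values and named edgeR for the case that counts were found. As counts are present, edgeR 4.0.16 in R 4.3.3 was the main test, with filterByExpr, TMM factors and the quasi-likelihood F test on a model with 1 mean per group over all 20 libraries. This left 18905 genes. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The SE of a log2 fold change was derived from the F statistic. The 5 contrasts were genotype within each diet, diet within each genotype, and the interaction. Totals of 75549139 to 108889938 counts per library give abundant genes small counting error, so the spread between libraries limits the precision. Floors of 3 counts cover counting error only. Nr1h3 was also compared with an exact permutation test of mean FPKM over the 252 arrangements of 10 libraries.

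In the text, 35 gene lists of pathways and cell type markers fixed before the data were examined were tested with camera of limma 3.58.1. The correlation was preset at 0.01 and then estimated, with adjustment over the lists within a contrast. Beside each list stand its members past the threshold over all genes and those adjusted over the list alone. KEGG pathways of 10 to 300 tested genes, as the deposited table assigns them, were tested with a one-sided hypergeometric test among tested genes with a pathway, per direction.

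The genes named in the text follow a rule fixed in advance. They are a core of 13 genes, the 6 largest rises and the 6 largest falls per comparison between groups, the 6 smallest p for the interaction, and the 3 members of each list with the smallest p over the 4 groups. The largest changes were taken among genes past the threshold with a mean FPKM of at least 2, groups that do not overlap and a gene name. Genes named outside this rule, such as Timd4, Per3, Map3k13 and Poc1b, were chosen after their values were seen.

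The procedure was tested on counts simulated for the 18905 genes with 200 changed genes per comparison. For 2-fold and 4-fold changes, edgeR recovered 29.9% and 74.2% for genotype on chow, 22.4% and 80.3% for genotype on HFD, 25.4% and 81.8% for diet in WT, 23.9% and 87.9% for diet in labelled LXRα-/-, and 1.5% and 39.4% for the interaction. At 1.5-fold it recovered 3.0% in the comparisons between groups and none for the interaction. A first criterion of 60% recovery at 4-fold was met in 4 of the 5 comparisons. It was replaced by a bound on the bias of the fold change, since the interaction estimates were unbiased and held no false call. False calls made up 0% to 7.3% of edgeR's calls and 25.4% to 31.8% of those of DESeq2 1.42.0. All 5 simulated lists of 20 genes raised 2-fold had an unadjusted camera p under 0.05, and so did 2 of 10 lists without a net change. Genes were simulated independently of each other, so this does not test the preset correlation of 0.01. The estimated correlations on HFD were, for instance, 0.429 for Kupffer cell markers and 0.007 for the circadian clock. For acute phase genes on chow the estimate was 0.661.

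Alternatives fixed in advance were another pseudocount, no filter or a stricter one, median-of-ratios, common-sum and quantile scaling, only the groups compared, no mean-variance trend, quality weights, the replicate number as a block, DESeq2, and leaving out each library. Added after seeing the data were limma on log2(FPKM + 1), library totals without TMM factors, leaving out mitochondrial genes and pseudogenes, the clock level or the mitochondrial share as a covariate, and leaving out 2 pairs of libraries. The clock level is the mean log2 CPM of Arntl and Npas2 minus that of Dbp and Per3.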

Results

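RNA labelled as liver was sequenced from mice at week 24 in a design that crossed genotype with diet. Wild-type (WT) mice and mice labelled LXRα-/- received chow or a high-fat diet (HFD), with 5 libraries in each of the 4 groups. LXRα is a nuclear receptor activated by oxysterols and encoded by Nr1h3. It is known to control genes of cholesterol efflux, fatty acid synthesis and phospholipid remodelling. The sample titles give the genotype as LXRα-/-, while a second label field calls the same animals a knockdown. Each library held 75549139 to 108889938 counts, and 16546 to 18254 genes had at least 10 counts.

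The WT chow libraries stood apart from the other 15 libraries. Mitochondrial genes took 4.71% ± 0.743 of the counts in WT chow (SD, n = 5), against 15.1% ± 4.09 in WT HFD, 22.0% ± 4.77 in labelled LXRα-/- chow and 16.9% ± 3.05 in labelled LXRα-/- HFD (SD, n = 5 each). No WT chow library exceeded 5.67%, and no other library was under 9.77%. Pseudogenes took 2.45% ± 0.469 of the counts in WT chow and 6.94% ± 1.35, 9.86% ± 2.43 and 7.63% ± 1.13 in the same 3 other groups. The first principal component, with 30.3% of the variance, placed the 5 WT chow libraries at one end. Comparisons that use WT chow therefore also compare libraries of different mitochondrial share.

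**Figure D1:**
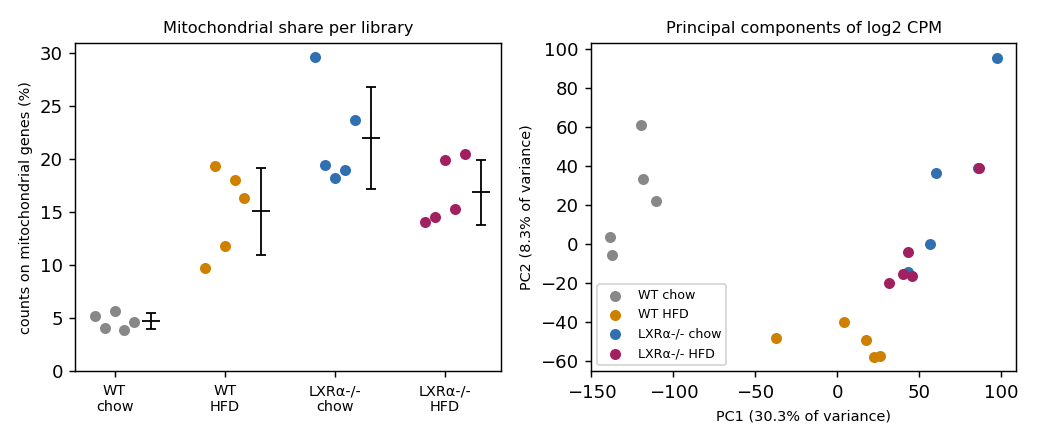
Left, share of counts on mitochondrial genes (%) in each of the 20 libraries by group, with a bar at the mean and its SD. Right, the same libraries on the first 2 principal components of log2 CPM, where the first carries 30.3% of the variance. The WT chow libraries lie between 3.89% and 5.67%, under all 15 others.

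Nr1h3 (ENSMUSG00000002108, chromosome 2, 91184061 to 91202834 in the file's coordinates) was not lower in the libraries labelled LXRα-/-. On chow its FPKM was 47.9 ± 23.4 in labelled LXRα-/- and 39.1 ± 4.88 in WT (SD, n = 5 each; two-sided exact permutation test, p = 0.492). On HFD it was 59.9 ± 27.9 in labelled LXRα-/- and 19.1 ± 3.79 in WT (SD, n = 5 each; two-sided exact permutation test, p = 0.0476, where the smallest possible p is 0.00794). Only library 4 of labelled LXRα-/- chow, at 7.9, and library 2 of labelled LXRα-/- HFD, at 10.3, lay under every WT library of their diet. The log2 fold change between genotypes was 0.26 (SE 0.43) on chow and 1.44 (SE 0.44) on HFD, with edgeR adjusted p of 0.662 and 0.145. Gene-level counts do not show which exons were read, so a transcript that lacks the deleted part could not be told from an intact one. Genotype names below are therefore the labels, and every direction drawn from them rests on the labels.

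Cd5l and Ddb2 followed the labels in all 20 libraries. Cd5l, a protein secreted by resident liver macrophages (chromosome 3, 87357881 to 87371073), had 78.5 ± 24.0 CPM (counts scaled to library size) in WT chow and 25.7 ± 4.81 in WT HFD. In labelled LXRα-/- it had 0.318 ± 0.473 on chow and 0.181 ± 0.122 on HFD (SD, n = 5 each). Ddb2, which recognises damaged DNA and lies near Nr1h3 (chromosome 2, 91211572 to 91236960), had 2.45 ± 0.457 and 3.53 ± 1.36 CPM in WT chow and WT HFD. It had 23.9 ± 8.61 and 23.3 ± 2.76 CPM in labelled LXRα-/- chow and HFD (SD, n = 5 each). The coordinates of Ddb2 overlap those of Acp2 (91202885 to 91214098), so the counts of the 2 genes may not be separate.

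**Figure D2:**
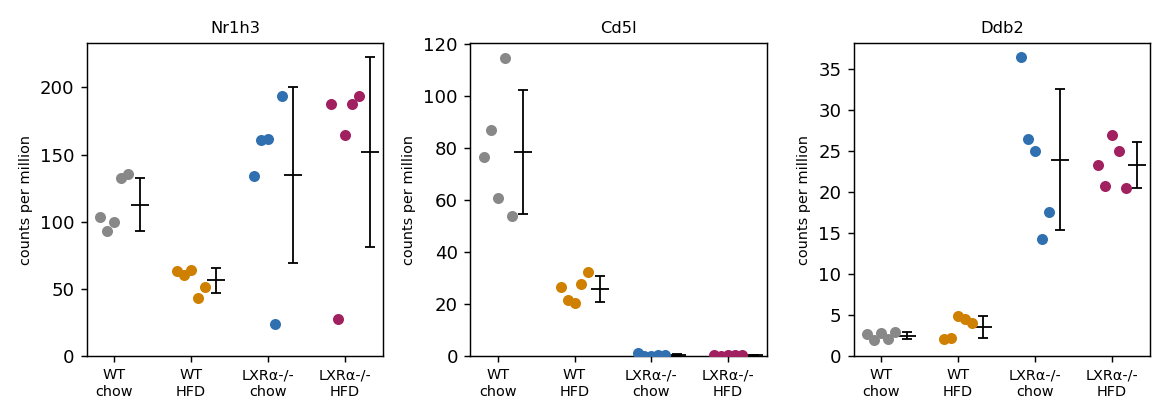
CPM (counts scaled to library size) of Nr1h3, Cd5l and Ddb2 in each library by group, 5 points per group, with a bar at the mean and its SD. Nr1h3 is low in 2 of the 10 libraries labelled LXRα-/-, whereas Cd5l is near 0 and Ddb2 is above every WT library in all 10.

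The comparison of genotypes on HFD asked which liver genes differ between mice labelled LXRα-/- and WT under a fat-rich diet. Cd5l, Pltp and Cyp2c70 were among the genes lower in labelled LXRα-/-, and Ddb2 and Acp2, which lie beside Nr1h3, were higher. Of the 28 tested neighbours of Nr1h3 these 2 rose and none fell (3 rises and 1 fall adjusted over the list alone; camera, adjusted p = 0.199). Ddb2 and Acp2 overlap each other, so their rises may not be separate. Of 18905 genes tested with edgeR's quasi-likelihood test, 86 passed an adjusted p of 0.05, and 48 rose while 38 fell in labelled LXRα-/-. The genes given as the largest changes here and below had a mean FPKM of at least 2, a gene name and groups that did not overlap. The largest falls were Cd5l, by a log2 fold change of -7.16 (SE 0.89, adjusted p = 0.00055), Pltp, Tmem248, Cyp2c70, Pdzk1ip1 and Spon2. Pltp transfers phospholipids between lipoproteins and is an LXR target. It changed by -2.56 (SE 0.55, adjusted p = 0.0438), and Cyp2c70, which makes the muricholic acids of mouse bile, by -2.13 (SE 0.28, adjusted p = 0.000757). Tmem248 changed by -2.19, Pdzk1ip1 by -1.86 and Spon2 by -1.52. The largest rises were Ddb2 by 2.72 (SE 0.28), Cyp3a59 by 2.68, Cd207 by 2.53, Fcgr4 by 2.22, Acp2 by 1.65 (SE 0.19) and Nr1d2 by 1.61. Cd207 is langerin, a lectin of dendritic cells, Fcgr4 is an Fc receptor, and Nr1d2 is a repressor of the clock.

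Among the LXR targets on HFD, Pltp was the member that passed over all genes, of 19 tested. The list gave 3 falls adjusted over the list alone, and its set test had an adjusted p of 0.411 (camera, downward, with a median of 0.01). Scd1, the stearoyl-CoA desaturase, differed by -1.80 (SE 0.54, adjusted p = 0.139), Acaca by -0.60, Fasn by -0.63, Lpcat3 by -0.31 and Srebf1 by -0.08. Abca1 differed by 0.72, Abcg5 by 0.37, Abcg8 by 0.30, Cd36 by 0.37, Cyp7a1 by 0.14 and Nr1h2 by 0.24, and none of these passed.

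The set test called 13 lists on HFD at the preset correlation and none with an estimated correlation, where adjusted p = 0.171 for Kupffer cell markers and the circadian clock, adjusted p = 0.259 for lipoprotein, adjusted p = 0.281 for fibrosis and adjusted p = 0.579 for the other 9. Of 15 Kupffer cell markers on HFD, 4 fell and none rose over all genes, against 8 falls and 1 rise adjusted over the list alone, and the median was -0.90 (camera, adjusted p = 1.34e-11 preset, 0.171 estimated). Besides Cd5l these were Timd4 at -5.14, a receptor for phosphatidylserine, Folr2 at -2.40 and Fcna at -0.90. Of 15 recruited macrophage markers, Itgax rose by 1.83 and Fabp5 changed by -2.53 (1 rise and 2 falls adjusted over the list alone; list adjusted p = 0.164). Of 19 lipoprotein genes 1 fell, Scarb1, the HDL receptor, at -0.85 (SE 0.17, adjusted p = 0.0318), against 4 adjusted over the list alone (camera, adjusted p = 0.000203 preset, 0.259 estimated). Nkg7 fell by 1.48 among 15 T and NK cell markers, where 1 also fell adjusted over the list alone (camera, adjusted p = 0.0229 preset, 0.579 estimated). The circadian clock list moved up with 2 rises, Nr1d2 and Per3, among 15 members (7 rises and 2 falls adjusted over the list alone; camera, adjusted p = 0.00647 preset, 0.171 estimated). That list holds genes of opposite phase, so its direction does not give a phase. Clock genes also split the libraries within groups: the log2 level of Arntl and Npas2 over Dbp and Per3 was -0.94 ± 1.85 in WT HFD and -5.68 ± 2.51 in labelled LXRα-/- HFD (SD, n = 5 each).

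No member passed over all genes in 9 further lists that the set test called on HFD at the preset correlation and not at the estimated one. Fatty acid synthesis had a median of -0.51 (2 falls adjusted over the list alone; adjusted p = 0.000737), fibrosis -0.49 (none adjusted over the list alone; adjusted p = 0.000389), oxidative phosphorylation -0.28 (none; adjusted p = 0.0039) and endothelial markers -0.31 (3 falls; adjusted p = 0.00243). Erythroid markers had -0.87 (3 falls; adjusted p = 0.00288), cholesterol synthesis -0.22 (1 fall; adjusted p = 0.027) and hepatocyte markers -0.39 (1 fall; adjusted p = 0.0191). The same held for male-biased liver genes at -0.25 (1 fall; adjusted p = 0.0334) and drug metabolism at 0.33 (6 rises adjusted over the list alone; adjusted p = 0.026). Leaving out any 1 WT HFD library gave 37 to 53 changed genes, leaving out library 1, 2, 4 or 5 of labelled LXRα-/- HFD gave 35 to 44, and DESeq2 called 533. With the clock level as a covariate 36 genes were called, 17 of them among the 86, and Pltp was not called. The calls of Pltp, Scarb1, Folr2, Fcna, Itgax, Nkg7, Cyp3a59 and Spon2 on HFD each ended when certain single libraries were left out. The groups did not overlap for 1423 genes (7.53%), where chance gives 0.794%. With library totals in place of TMM factors 83 rose and 17 fell, as the median of all genes moved from 0.03 to 0.23.

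On chow, 8197 of 18905 genes (43.4%) differed between labelled LXRα-/- and WT, 4225 higher and 3972 lower (edgeR, adjusted p under 0.05). The WT libraries of this comparison are those with the low mitochondrial share. Of the fixed lists, 12 were called at the preset correlation, among them acute phase and cholesterol synthesis downward and B and plasma cell markers upward. None of the 12 was called with an estimated correlation (camera, adjusted p = 0.821 for each). The largest falls were Mup-ps17, Saa2 at -8.39 (SE 1.24, adjusted p = 2.39e-05), Cd5l at -7.99 (SE 0.92, adjusted p = 1.68e-06), Scamp4 at -7.79, Raver1 at -7.27 and Saa1 at -6.90. Mup-ps17, a pseudogene that shares sequence with the major urinary protein genes, had no count in the 5 libraries of labelled LXRα-/- chow and was at least 440-fold lower against a floor of 3 counts over the group. The largest rises were Cyp2b9 at 8.51 (SE 1.52, adjusted p = 0.000168), the immunoglobulin gene Ighg1 at 5.96 and 4 small RNA genes, Snora81 at 7.02, Snora30 at 6.17, Rnu3b4 at 6.08 and Rnu3b2 at 5.93. Cyp2b9 is a cytochrome P450 of drug and steroid metabolism, with close paralogs, and was at 6.91 without library 3 of labelled LXRα-/- chow. Without library 5 of that group Saa2 was at -9.60 and Saa1 at -8.17, without library 2 of WT chow they were at -7.63 and -6.13, and without library 1 of labelled LXRα-/- chow Cd5l was at -9.50. Raver1 had counts in that library alone of the 5. Small RNAs are poorly captured by poly(A) selection and lie within or beside other transcripts, so their counts are uncertain.

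Of 18 acute phase genes on chow 15 fell and 1 rose (16 falls and 1 rise adjusted over the list alone), with a median of -2.51 (camera, adjusted p = 2.71e-05 preset, 0.821 estimated). The adjusted p of the lists that follow are at the preset correlation, and each was 0.821 at the estimated one. Saa1 had 12196 ± 13136 CPM in WT chow and 102 ± 135 in labelled LXRα-/- chow (SD, n = 5 each), and Fga, a fibrinogen chain, changed by -5.01, or -4.35 without library 2 of WT chow. Of 25 cholesterol synthesis genes 16 fell and none rose, with the same counts adjusted over the list alone (median -1.25, adjusted p = 8.52e-05). Among them were Dhcr7 at -4.04 and Pmvk at -2.15. Fatty acid synthesis had 10 falls and 1 rise among 20 genes, the same adjusted over the list alone (adjusted p = 0.0442), including Me1 at -4.03, Acacb at -2.91 and Fads1 at -1.60. Of 22 fatty acid oxidation genes 10 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.00692), with Hadhb at -3.46, Ppara at -2.24 and Cpt1a at -2.16. Lipid droplet and triglyceride genes had 9 falls and 4 rises among 20, the same adjusted over the list alone (adjusted p = 0.0486), with Plin2 at -2.18, Plin5 at -1.95 and Plin3 at -1.77.

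Bile acid genes had 9 falls and 4 rises among 18 on chow, the same adjusted over the list alone (adjusted p = 0.0442), led by Cyp2c70 at -3.78, the bile acid importer Slc10a1 at -2.61 and Acox2 at -1.84. Of 15 hepatocyte markers 8 fell and none rose (adjusted p = 0.0182), including Cps1 at -2.15, Trf at -1.57 and Serpina1a at -1.27. Oxidative phosphorylation had 10 falls and 2 rises among 21 nuclear genes (adjusted p = 0.0442), with Atp5b at -3.29, Atp5a1 at -2.40 and Sdha at -1.65. KEGG's set of that name had 33 of 105 genes among those that rose (20.2 expected, hypergeometric test, adjusted p = 0.066), which did not pass. With mitochondrial share as a covariate the fixed list reversed its sign and did not pass. Kupffer cell markers had 11 falls among 15 (median -1.39, adjusted p = 0.000412), with Folr2 at -2.52 and Fcna at -1.35. In these 3 lists the counts were the same adjusted over the list alone. Upward lists were T and NK cell markers, with 7 rises of 15, B and plasma cell markers, with 8 of 12, and antigen presentation, with 6 of 9 (7, 8 and 7 adjusted over the list alone). Their adjusted p were 0.0311, 0.00458 and 0.0342, and they were led by Trbc2 at 2.60, Lck at 2.38, Igkc at 3.83 and H2-Aa at 1.47.

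LXR targets moved both ways on chow, with 5 rises and 6 falls among 19 genes (6 and 6 adjusted over the list alone). Their median was -0.02 and their mean -0.07, while camera gave an upward direction at an adjusted p of 0.903. Abca1, the cholesterol exporter, rose by 0.64 (SE 0.26, adjusted p = 0.0492). Lpcat3, a phospholipid remodelling enzyme, fell by 1.29 (SE 0.28, adjusted p = 0.000932), Scd1 by 1.80 (SE 0.54, adjusted p = 0.0113), Acaca by 0.70, Smpdl3a by 1.37 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 2.54 (SE 0.66, adjusted p = 0.00397). Cd36, a fatty acid transporter, fell by 1.59. The calls of Abca1 and Acaca ended when certain single libraries were left out. Srebf1 differed by 0.57, Nr1h2 by 0.64, Abcg5 by 0.70, Fasn by -0.08, Abcg8 by -0.02 and Pltp by 0.02, and none of these passed.

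The other 22 lists had camera adjusted p of 0.128 to 0.942 on chow. Members of several changed nonetheless: the unfolded protein response had 9 falls and 3 rises among 16 genes (10 and 3 adjusted over the list alone), with Hyou1 at -3.22, Xbp1 at -3.16 and Atf4 at 0.94, and glucose metabolism 8 falls and 3 rises among 17 (8 and 3), with Fbp1 at -3.08 and Irs1 at 1.95. Drug metabolism had 6 falls and 4 rises among 16 (6 and 4 adjusted over the list alone), with Cyp2b10 at -4.99 and Cyp2c29 at -3.25. Cyp2b10 was at -4.16 without library 5 of WT chow and -5.79 without library 3 of labelled LXRα-/- chow. Recruited macrophage markers had 5 falls and 3 rises among 15 (5 and 3 adjusted over the list alone), with Fabp5 at -5.98 and Itgax at 3.03. Among KEGG pathways, the genes that fell were enriched for lysosome (54 of 113, 30.5 expected, adjusted p = 0.000343), protein processing in the endoplasmic reticulum (65 of 146, 39.4 expected, adjusted p = 0.000343) and the citrate cycle (18 of 25, 6.8 expected, adjusted p = 0.000343), the first 3 of at least 15 pathways that passed. Those that rose passed for asthma (9 of 12, 2.3 expected) and the intestinal network for IgA production (16 of 32, 6.2 expected), each with an adjusted p of 0.0128. Retrograde endocannabinoid signaling (36 of 104, 20 expected, adjusted p = 0.0142) and ribosome biogenesis (24 of 65, 12.5 expected, adjusted p = 0.0468) passed as well. Without library 1 of labelled LXRα-/- chow the set test called 5 lists. The groups did not overlap for 5530 genes (29.2%), where chance gives 0.794%. With mitochondrial share as a covariate 183 genes were called on chow, and that share nearly coincides with the groups. With FPKM rescaled to a common sum 1511 rose and 5644 fell, as the median of all genes moved from 0.08 to -0.47.

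The genotype effects of the 2 diets were compared gene by gene, with no library in common. Across 18905 genes, which are not independent replicates, the log2 fold changes had Pearson's r of 0.337 (jackknife SE 0.113 over libraries) and Spearman's rho of 0.384. That r was 0.156 without a filter on low values and 0.196 with the clock level as a covariate. Called on both diets were 34 genes that rose, against 10.7 for independent lists, and 26 that fell, against 8.0, while 6 went in opposite directions, against 18.6. Cd5l, Folr2, Fcna, Timd4, Scarb1, Cyp2c70 and Tmem248 fell on both diets, and Ddb2, Fcgr4, Itgax and Nr1d2 rose on both. The 6 opposite genes fell on HFD and rose on chow for Spon2 (-1.52 and 1.95), Nkg7 (-1.48 and 1.81), Crygn (-1.35 and 0.93) and Smim22 (-1.33 and 1.25). Poc1b (2.19 and -2.06) and Rnf128 (4.70 and -3.12) went the other way.

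**Figure D3:**
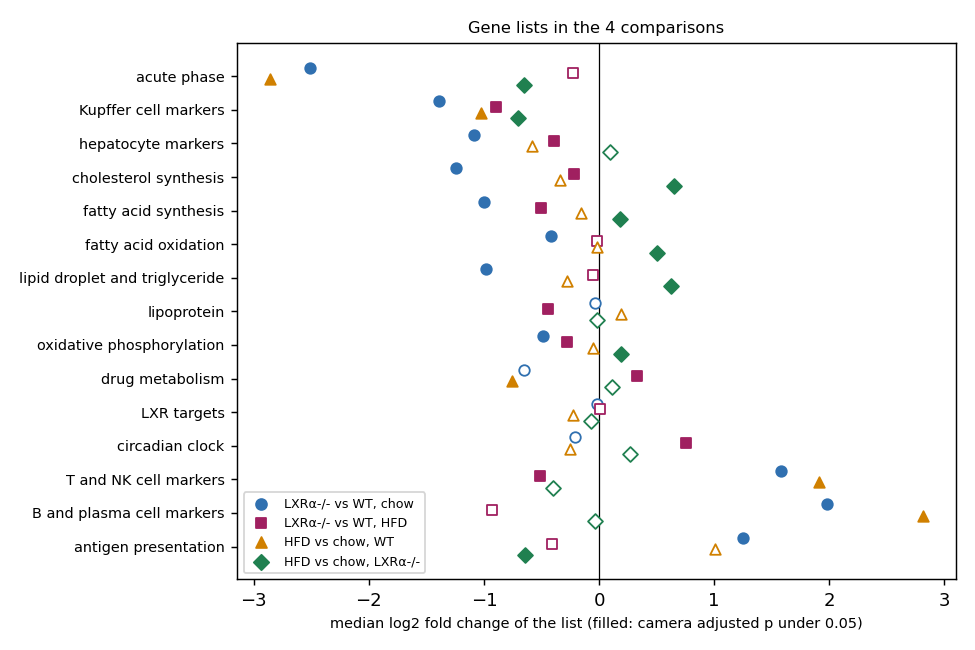
Median log2 fold change of 15 gene lists (horizontal axis) in the 4 comparisons between groups. Filled symbols mark lists with a camera adjusted p under 0.05 at a preset correlation of 0.01. None of them passed with an estimated correlation. Acute phase genes lie at -2.51 for genotype on chow and -2.86 for diet in WT, and at -0.23 for genotype on HFD.

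In WT mice, HFD changed 5547 genes against chow, 2706 upward and 2841 downward (edgeR, adjusted p under 0.05). This comparison again uses the WT chow libraries. Of the 6 largest falls 4 were serum amyloid or metallothionein genes, and 3 of the 6 largest rises were immunoglobulin genes, whose size rests in part on library 5 of WT HFD. The largest falls were Saa2 at -9.99 (SE 1.32, adjusted p = 1.82e-05), Saa1 at -9.17 (SE 1.21), Lcn2 at -7.59, the metallothioneins Mt2 at -7.44 (SE 0.79) and Mt1 at -5.88, and Ugt1a5 at -5.69. The largest rises were H2ac19, Cidea at 5.62 (SE 1.36, adjusted p = 0.00399), Ighg2c at 5.19, Igkc at 4.85, Iglc2 at 4.35 and Fgf21 at 4.10 (SE 0.66, adjusted p = 0.000118). The histone gene H2ac19, one of a family of near-identical copies, had no count in WT chow and was at least 2550-fold higher against a floor of 3 counts over the group. Without library 5 of WT HFD Ighg2c was at 2.50, Iglc2 at 2.46, Igkc at 3.97 and Mt1 at -6.48, and without library 2 of WT HFD Cidea was at 4.32. Without library 2 of WT chow Saa2 was at -9.23, Saa1 at -8.40 and Lcn2 at -6.63, without library 4 Mt2 was at -6.78, and without library 1 of WT HFD Ugt1a5 was at -6.30. Cidea coats lipid droplets and Fgf21 is a liver hormone of nutrient stress.

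The set test called 5 lists for diet in WT at the preset correlation and none with an estimated correlation, where adjusted p = 0.595 for acute phase and B and plasma cell markers, adjusted p = 0.675 for T and NK cell markers and adjusted p = 0.923 for the other 2. Acute phase genes had 16 falls among 18 in WT on HFD, the same adjusted over the list alone (median -2.86, camera, adjusted p = 4.5e-11 preset, 0.595 estimated). Kupffer cell markers had 10 falls of 15 (12 adjusted over the list alone; adjusted p = 0.00111), and drug metabolism 8 falls and 2 rises of 16 (9 and 2; adjusted p = 0.0242), led by Cyp2b10 at -4.87 (-4.04 without library 5 of WT chow), Cyp2c29 at -2.77 and Cyp3a13 at -2.12. B and plasma cell markers had 11 rises of 12 (12 adjusted over the list alone; adjusted p = 2.71e-06 preset, 0.595 estimated), and T and NK cell markers 6 of 15 (9; adjusted p = 0.000542), with Trbc2 at 2.32 and Nkg7 at 2.31. Erythroid markers, a sign of blood in the tissue, had a median of 1.35 in the same comparison, with 2 rises and no fall of 7 (2 adjusted over the list alone; adjusted p = 0.0962 preset, 0.923 estimated), and Hba-a1 at 2.39 was 1 of the 2.

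Of the core genes in WT, Srebf1, the regulator of lipogenesis, rose by 0.94 (SE 0.34, adjusted p = 0.0452) and Pltp by 1.96 (SE 0.53, adjusted p = 0.00892) on HFD, and the call of Srebf1 ended when certain single libraries were left out. Nr1h3 had 39.1 and 19.1 FPKM on chow and HFD (edgeR, adjusted p = 0.0914). Fasn differed by 1.12, Scd1 by -0.59, Acaca by -0.31, Lpcat3 by -0.69, Abca1 by -0.23, Abcg5 by 0.47, Abcg8 by -0.42, Cyp7a1 by -0.95, Cd36 by -0.94 and Nr1h2 by 0.49, and neither these nor Nr1h3 passed. The other 30 lists had camera adjusted p of 0.0582 to 0.986. Lipid genes moved both ways: fatty acid oxidation had 5 rises and 7 falls of 22 (6 and 9 adjusted over the list alone), with Hadhb at -2.70 and Cpt1a at -1.55, and cholesterol synthesis 2 rises and 3 falls of 25 (2 and 3). KEGG's oxidative phosphorylation was enriched among the genes that rose (42 of 105, 12.9 expected, adjusted p = 1.01e-10), while the fixed list of nuclear respiratory chain genes had 7 rises and 6 falls of 21 (7 and 7 adjusted over the list alone), with Atp5b at -2.42. Of 14 pathways enriched among the genes that rose, others were ribosome (34 of 106, 13 expected, adjusted p = 3.9e-06) and hematopoietic cell lineage (23 of 80, 9.8 expected, adjusted p = 0.00187). Complement and coagulation (34 of 78, 15.4 expected, adjusted p = 0.000365) and the citrate cycle (15 of 25, 4.9 expected, adjusted p = 0.00167) were among 5 enriched in the genes that fell. With mitochondrial share as a covariate 1462 genes were called, 1350 of them among the 5547. With the clock level as a covariate 1967 were called, 1860 of them among the 5547. With FPKM rescaled to a common sum 922 rose and 4855 fell, as the median of all genes moved from 0.02 to -0.37.

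In mice labelled LXRα-/-, 3 genes differed between HFD and chow, all higher on HFD: Map3k13, a stress kinase, by 1.66 (SE 0.23, adjusted p = 0.0135), Poc1b by 2.58 (SE 0.40, adjusted p = 0.0267) and Papola, the poly(A) polymerase, by 1.55 (SE 0.26, adjusted p = 0.0462). The call of Papola ended in 15 of the 20 omissions of a single library. Map3k13 and Poc1b were named after their values were seen. At an unadjusted p of 0.05, 1278 of the 18905 genes differed, and DESeq2 called 66. No core gene passed, with Cyp7a1 at 1.73 (SE 0.64, adjusted p = 0.621), Cd36 at 1.02, Scd1 at -0.59, Pltp at -0.62, Fasn at 0.56, Srebf1 at 0.29 and Nr1h3 at 0.18.

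The set test called 11 lists between the diets in labelled LXRα-/-, none with a member that passed over all genes. None was called with an estimated correlation, with adjusted p = 0.282 for cholangiocyte markers, adjusted p = 0.309 for Kupffer, cholesterol, fatty acid oxidation and lipid droplet genes, and adjusted p = 0.409 to 0.652 for the other 6. At the preset correlation, upward were cholesterol synthesis (median 0.65, 2 rises adjusted over the list alone, adjusted p = 1.64e-10), with Dhcr7 at 0.71, fatty acid oxidation (median 0.50, none adjusted over the list alone, adjusted p = 1.79e-09), with Cpt1a at 0.86, and lipid droplet and triglyceride (median 0.62, 1 rise, adjusted p = 2.94e-07), with Plin2 at 0.79. Fatty acid synthesis had a median of 0.18 (3 rises, adjusted p = 0.0334), with Fads1 at 1.01, and oxidative phosphorylation 0.19 (none, adjusted p = 0.00921). Downward were Kupffer cell markers (median -0.70, 6 falls adjusted over the list alone, adjusted p = 1.1e-07), with Folr2 at -1.28, acute phase (median -0.65, none, adjusted p = 1.11e-05), antigen presentation (median -0.64, 1 fall, adjusted p = 0.00027), cholangiocyte markers (median -0.67, 1 fall, adjusted p = 0.00266), with Krt19 at -1.07, chemokines and cytokines (median -0.33, none, adjusted p = 0.0195) and fibrosis (median -0.17, 1 fall, adjusted p = 0.0399). The groups did not overlap for 157 genes (0.83%), where chance gives 0.794%. Without library 3 of labelled LXRα-/- HFD 15 genes were called, without library 4 of WT HFD 5, and without library 1, 2 or 3 of labelled LXRα-/- chow or library 4 or 5 of labelled LXRα-/- HFD none. With library 1 of WT chow, library 5 of labelled LXRα-/- chow or library 1 of labelled LXRα-/- HFD left out 1 was called. The set test called 6 lists without library 1 of labelled LXRα-/- chow and 18 without library 4.

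The interaction tested whether the diet effect differed between genotypes, as the effect in labelled LXRα-/- minus that in WT. It passed for 3661 genes, 1936 with a positive and 1725 with a negative value (edgeR, adjusted p under 0.05). The contrast uses the WT chow libraries, so an offset of those libraries from any cause cannot be told apart from a diet effect that depends on genotype. Among the 6 genes with the smallest p and a mean FPKM of at least 2 were Ssrp1 at 2.92 (SE 0.25, adjusted p = 4.25e-06), Acad11 at 2.98, Mir8114 at 4.73, Polr2m at 2.74 and Ptpa at 3.05. Of the core genes, Cyp7a1 had an interaction of 2.68 (SE 0.89, adjusted p = 0.0405), Cd36 of 1.96 (SE 0.67, adjusted p = 0.0437) and Pltp of -2.58 (SE 0.74, adjusted p = 0.0185). With the clock level as a covariate the interaction of Cyp7a1 was -1.11 (adjusted p = 0.692) and that of Cd36 0.72 (adjusted p = 0.78), while Pltp still passed. With mitochondrial share none of the 3 passed. The calls of Cyp7a1 and Cd36 ended in 11 and 15 of the 20 omissions of a single library, while Nr1h3 at 1.18, Lpcat3 at 0.97, Scd1 at -0.01 and Fasn at -0.56 did not pass.

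The set test called 7 lists for the interaction at the preset correlation and none with an estimated correlation (adjusted p = 0.823 to 0.873). Acute phase was positive in 11 of 18 genes (11 adjusted over the list alone; adjusted p = 3.45e-06), with Saa2 at 8.09 and Fga at 3.91, cholesterol synthesis in 7 of 25 (7; adjusted p = 0.000744), fatty acid oxidation in 7 of 22 with 2 negative (7 and 2; adjusted p = 0.0188), with Hadhb at 2.93 and Ppara at 2.61, and drug metabolism in 6 of 16 with 2 negative (8 and 2; adjusted p = 0.0383). Negative were B and plasma cell markers in 8 of 12 (10 adjusted over the list alone; adjusted p = 5.46e-05), with Igkc at -5.37, T and NK cell markers in 5 of 15 (7; adjusted p = 0.000354), with Nkg7 at -3.29, and antigen presentation in 6 of 9 (8; adjusted p = 0.00171), with H2-Ab1 at -2.05. Without library 2 of WT chow Saa2 was at 7.33 and Fga at 3.24. Saa2 was at 9.30 without library 5 of labelled LXRα-/- chow and 7.05 without library 4 of labelled LXRα-/- HFD, and Igkc at -4.48 without library 5 of WT HFD. The interaction count was 76 with mitochondrial share and 741 with the clock level as a covariate. With library totals in place of TMM factors 2301 were positive and 1234 negative, and with FPKM rescaled to a common sum 4970 and 456.

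The diet effects in the 2 genotypes had Pearson's r of -0.09 and Spearman's rho of -0.16 across the 18905 genes. The genes changed by HFD in WT had a median of -0.10 in the same direction in labelled LXRα-/-, against 1.18 in WT. Labelled LXRα-/- chow and WT HFD, both set against WT chow, had fold changes correlated at r of 0.813 with a covariance of 1.33. Unchanged groups simulated against those shared controls gave 0.46 and 0.131, and splitting the WT chow libraries between the 2 comparisons gave a median r of 0.689. Compared directly, labelled LXRα-/- chow and WT HFD differed in 703 genes.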

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

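Of the tests here, those of clock phase within groups and of a gradient marked by the mitochondrial share were written before their results were seen, and the other tests, with the spread drawn for the clock genes, were chosen after. Within each group of 5 libraries, the gap between an extreme library and its nearest neighbour was divided by the group's range and set against Dixon's critical value of 0.71. Over the core genes, the largest changes and the library measures, 36 of 228 groups exceeded it, where chance gives about 1 in 20, or 11.4.

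Among the library measures, the pseudogene share of labelled LXRα-/- chow 1 stood apart with a ratio of 0.743, at 14.1% against a mean of 8.81% in the other 4. The clock level stood apart in WT chow 2 (0.743), labelled LXRα-/- chow 2 (0.729) and labelled LXRα-/- HFD 3 (0.789). Labelled LXRα-/- HFD 3 was also apart for Snora81 (0.805), Snora30 (0.949), Rnu3b4 (0.913), Rnu3b2 (0.89), Raver1 (0.959) and Cyp3a59 (0.795). Labelled LXRα-/- HFD 2 was apart for Nr1h3 (0.826), at 27.2 CPM against a mean of 183 in the other 4, and for H2ac19 (0.722). Labelled LXRα-/- HFD 1 was apart for Mup-ps17 (0.868) and labelled LXRα-/- HFD 4 for Saa2 (0.9).

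In labelled LXRα-/- chow, library 1 was apart for Cd5l (0.832), Raver1 (a ratio of 1, as the other 4 had no count) and Tmem248 (0.755), and library 2 for Acp2 (0.785). Library 3 was apart for Cyp2b9 (0.875) and Ugt1a5 (0.954), and library 4 for Cidea (0.919). Library 5 was apart for Saa2 (0.78), Saa1 (0.8), Lcn2 (0.711), Mt2 (0.762) and H2ac19 (a ratio of 1, as the other 4 had no count). The Acp2 of labelled LXRα-/- chow 2, at 84.5 CPM, lay within the 80.1 to 88.5 of labelled LXRα-/- HFD. That library also lay near labelled LXRα-/- HFD 3 on the first 2 principal components (86.08 and 38.9 against 86.77 and 39.15). Their clock levels were -1.38 and -1.28. Whether diet labels were mixed within labelled LXRα-/- was not tested. In WT HFD, library 5 was apart for Abcg8 (0.741), Ighg2c (0.974), Iglc2 (0.917), Mt2 (0.794) and Mt1 (0.791), and library 3 for Mup-ps17 (0.853). In WT chow, library 5 was apart for Snora81 (0.948, at 0 CPM against a mean of 0.0108 in the other 4) and Raver1 (0.717). Library 3 was apart for Ighg2c (0.712) and library 4 for Mt2 (0.716).

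The test of the interaction itself passed for 3661 genes, among them Cyp7a1 by 2.68, Cd36 by 1.96 and Pltp by -2.58 among the core genes. WT chow enters this contrast. An offset of those libraries from any cause therefore cannot be told apart from a diet effect that depends on genotype. With mitochondrial share as a covariate, which nearly coincides with WT chow, 76 genes passed. The calls of Cyp7a1 and Cd36 ended in 11 and 15 of the 20 omissions of a single library. With the clock level as a covariate the interaction of Cyp7a1 was -1.11 and that of Cd36 0.72, and neither passed. Other splits of the same libraries tested whether such counts arise by chance, with 60 splits drawn per comparison, the real one included. Chance is argued against for genotype on chow (8197 genes, at most 899 in another split), genotype on HFD (86, at most 5), diet in WT (5547, at most 928) and the interaction (3661, at most 2). In each of these only 1 of the 60 splits, the real one, reached its count, which is the smallest share that the draw allows. For diet in labelled LXRα-/- chance cannot be excluded, as 4 of the 60 splits gave 3 genes or more, and the highest other gave 6.

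Nr1h3 was not lower in the libraries labelled LXRα-/-. Labels mixed between libraries were set against 267 genes whose 10 labelled LXRα-/- libraries all lay apart from the 10 WT libraries. Of these 187 were higher and 80 lower, where 0.2 are expected by chance. The first principal component also parted them, with WT at 26.04 or less and labelled LXRα-/- at 31.64 or more. Genes that follow that component separate the labels whatever its cause, so the 267 do not decide. Cd5l had 20.4 CPM or more in every WT library and 1.15 or less in those labelled LXRα-/-. This 1 gene, chosen after its values were seen, speaks against mixed labels. What stays open is that a transcript of the targeted allele may still be counted: 8 of the 10 libraries labelled LXRα-/- had Nr1h3 at or above the WT mean of their diet. Gene-level counts hold no exon that would decide it, so such a transcript and an intact one cannot be told apart. A knockdown, as a second label field has it, was not tested separately.

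The WT chow libraries stood apart from all others. A diet effect shared by both genotypes as the whole cause is argued against by the genes changed in WT, whose median in the WT direction was -0.1 in labelled LXRα-/-. From chow to HFD the mitochondrial share rose in WT, from 4.71% to 15.1%, and fell in labelled LXRα-/-, from 22.0% to 16.9%. Genes that follow that share would move in opposite directions, so the median cannot speak against a shared effect as part of the cause. Without mitochondrial genes and pseudogenes, 7267 of 16883 genes were called for genotype on chow, 7235 of them among the 8197. The calls are thus not mainly these genes themselves. TMM factors already limit the pull of such genes on the scaling, so this omission could hardly change the other calls. It does not test what the mitochondrial share marks. A gradient of RNA handling or tissue state marked by the mitochondrial share may account for part of the pattern. Across the 8197 genes called on chow, which are not independent replicates, the slope on that share within the other 15 libraries correlated with the fold change on chow at r of 0.553. Permuting the share within groups 1000 times gave -0.441 to 0.483 for the central 95%, and leaving out 1 library gave 0.402 (without WT HFD 1) to 0.58. The shares of WT chow do not overlap those of any other library, and the labels give no batch. A response to diet that is specific to WT mice, and a genotype effect specific to chow, stay open as well.

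Clock genes differed between WT HFD and labelled LXRα-/- HFD. Genotype alone is argued against by the WT chow libraries, whose mean clock level lay at -5.06 relative to WT HFD, against an SD of 1.85 in WT HFD. A second explanation was that libraries differ in clock phase within groups. By Pearson's r the 7 other clock genes had the sign that such a difference predicts, and 2 of 7 followed the level with r beyond 0.5. The rule written beforehand asked for at least 6 of 7, and 2 of 7 lay in the range that it counted against this explanation. Libraries drawn again within groups 1000 times, a spread added after that result, gave 0 to 6 genes for the central 95%. As that spread reaches 6, a difference in phase is not excluded. Over 20 libraries, centred within groups, Nr1d1 had Pearson's r of -0.62 and Spearman's rho of -0.72 (permutation p = 0.0041, adjusted p = 0.014, r of -0.59 without the 2 farthest libraries). Ciart had r of -0.77 and rho of -0.63 (permutation p = 8e-05, adjusted p = 0.00056, r of -0.51 without the 2 farthest). The other 5 had r of 0.4 for Clock, 0.47 for Nfil3, -0.44 for Tef, -0.29 for Nr1d2 and -0.12 for Hlf, with rho of 0.36, 0.28, -0.27, -0.39 and 0.08. Without the 2 farthest libraries r was 0.08, 0.11, 0.02, -0.26 and 0.12, so Tef and Hlf lost the sign and Clock and Nfil3 rest on those libraries. The time of collection is not in the labels, and an effect of diet on the clock in WT mice stays open. In that comparison 2 of the 15 clock genes rose and 5 fell (camera, adjusted p = 0.495). The list holds genes of opposite phase, so a set test in 1 direction can miss a shift of phase. The mean clock level was -6.00 in WT chow and -0.94 in WT HFD.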

How the results depend on the processing

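Added after seeing the data were limma on log2(FPKM + 1), library totals without TMM factors, leaving out mitochondrial genes and pseudogenes, both covariates and the 2 omissions of library pairs; the other alternatives were fixed before. Except where a construction is named, the cause of a change was not tested. Counts within 1.5 times the reported one are taken as kept.

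For genotype on chow (8197), the count was 4073 with a mean FPKM of at least 2, where fewer genes are tested, and 183 with mitochondrial share as a covariate, which nearly coincides with WT chow. It ranged from 7400 to 8290 with 1 library left out. For diet in WT (5547) it was 3266, 1462 with mitochondrial share and 1967 with the clock level, and 4655 to 5775 with 1 library left out. For the interaction (3661) it was 76 with mitochondrial share and 741 with the clock level, and 3071 to 4146 with 1 library left out.

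For genotype on HFD (86), the count was 48 without a filter, 34 with a mean FPKM of at least 2, 147 with FPKM rescaled to a common sum, 153 with quantile normalization, 348 with only the groups compared, 683 with quality weights, 42 with the replicate block, 533 with DESeq2, 227 with limma on log2(FPKM + 1), 36 with the clock level (17 of them among the 86), 43 without the 2 labelled LXRα-/- libraries of lowest Nr1h3 and 132 without labelled LXRα-/- chow 1 and 5. It ranged from 35 to 125 with 1 library left out: 38, 47, 53, 37 and 50 without WT HFD 1 to 5, and 44, 35, 43 and 36 without labelled LXRα-/- HFD 1, 2, 4 and 5, where fewer samples remain. DESeq2's share of false calls was higher on simulated counts.

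For diet in labelled LXRα-/- (3), the count was 1 with a mean FPKM of at least 2, with only the groups compared or with the replicate block, 66 with DESeq2, and 0 with quantile normalization, either covariate or without labelled LXRα-/- chow 1 and 5. With 1 library left out it ranged from 0 to 15: 15 without labelled LXRα-/- HFD 3, 5 without WT HFD 4, 1 without WT chow 1, labelled LXRα-/- chow 5 or HFD 1, and 0 without labelled LXRα-/- chow 1, 2 or 3 or HFD 4 or 5.

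Nr1h3 on chow (0.26) was -0.01 with the other pseudocount, -0.51 with FPKM rescaled, -0.03 with mitochondrial share and 0.53 (adjusted p = 0.0153) without the 2 libraries of lowest Nr1h3, and 0.09 to 0.53 with 1 library left out. On HFD (1.44) it passed with DESeq2 at 1.42 (adjusted p = 0.0412) and without those 2 libraries at 1.71 (adjusted p = 8.96e-05), and was 1.34 to 1.71 with 1 library left out. The 2 libraries were chosen by Nr1h3 itself, so the higher values without them follow from that choice and test nothing. The correlation of genotype effects (0.337) was 0.156 without a filter and 0.196 with the clock level, and 0.239 to 0.334 with 1 library left out. That of diet effects (-0.09) was -0.032 without a filter, -0.196 with the clock level and -0.238 with mitochondrial share, and -0.107 to -0.052 with 1 library left out.

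Of the lists on chow (12), 2 were called with a mean FPKM of at least 2, 4 with quantile normalization or limma on log2(FPKM + 1), 5 with the other pseudocount, 6 with FPKM rescaled, quality weights or mitochondrial share, 7 without labelled LXRα-/- chow 1 and 5, and 5 (without labelled LXRα-/- chow 1) to 12 with 1 library left out. On HFD (13), 6 were called with a mean FPKM of at least 2 or quantile normalization and 20 with the clock level, and 9 to 16 with 1 library left out. For diet in WT (5), 1 and 3 were called with the same 2 settings, and 4 to 7 with 1 library left out. For diet in labelled LXRα-/- (11), 4 were called without labelled LXRα-/- chow 1 and 5, and 6 (without labelled LXRα-/- chow 1) to 18 (without chow 4) with 1 library left out. For the interaction (7), 3 were called with a mean FPKM of at least 2 and 4 with the other pseudocount, FPKM rescaled or limma on log2(FPKM + 1), and 5 to 10 with 1 library left out.

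Signs reversed with mitochondrial share as a covariate on chow, among other results, for the oxidative phosphorylation list (0.23), Mup-ps17 (5.63), Csf3r (-0.12), Myh4 (1.47) and Hbb-bs (0.96), and with the clock level for the interactions of Cyp7a1 (-1.11) and Hmox1 (-0.03). None of these passed there. Among called named genes, 4554 values kept direction and side of the threshold, 522 no longer passed and 7 reversed, and 5552 and 288 with 1 library left out. For called lists these were 660, 148 and 1, and 895 and 65 with 1 library left out. These totals pool settings that differ widely. With mitochondrial share as a covariate 68 values of named genes were kept, 219 no longer passed and 5 reversed. With the clock level 185 were kept, 105 no longer passed and 2 reversed. The next largest loss was 32 values, with FPKM rescaled to a common sum. Same-number libraries of different groups were no more alike than others, with a mean r of 0.001 over 30 pairs.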

Other observations

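All tests here were chosen after the results were seen, and genes named here were chosen after their values were seen. Several single genes known from myeloid cells differed in the libraries labelled LXRα-/- on both diets, without a test of such genes as a group. The fixed list of recruited macrophage markers moved both ways, with 3 rises and 5 falls on chow (camera, adjusted p = 0.388) and 1 rise and 1 fall on HFD (adjusted p = 0.164). Clec4b1 was higher by 5.19 on chow and 5.08 on HFD, Sirpb1a by 4.50 and 4.12, Adamdec1 by 2.11 and 2.57, Fcgr4 by 1.39 and 2.22 and Clec4a1 by 1.21 and 1.34. Ccr3, with no count in WT HFD, was at least 135-fold higher on HFD, and H2-M2, with no count in either WT group, was at least 134-fold higher on chow and 62.4-fold on HFD, against a floor of 3 counts over the group. Timd4 was lower, at -2.98 and -5.14, and Cd5l at -7.99 and -7.16. The genes given with values here separated the 10 libraries labelled LXRα-/- from the 10 WT libraries.

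One hypothesis is that fewer Kupffer cells may account for the near loss of Cd5l. The other 14 Kupffer cell markers had a median of -0.7 on HFD (SD 1.47), from -5.14 for Timd4 to 0.58 for Slc40a1, and 13 of 14 were below 0. That median lies above the -7.16 of Cd5l by more than 2 SD, so the markers as a set did not fall as far as Cd5l. The list also holds genes of macrophages in general, such as Adgre1 and Csf1r. It therefore cannot decide on the number of resident Kupffer cells. A lower share of Kupffer cells, and a change of state within them, stay open.

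A second hypothesis is that Ddb2 and Acp2, the neighbours of Nr1h3, could be higher because sequence of another strain surrounds the targeted gene. Ddb2 was higher on both diets, while Acp2 was higher on HFD and differed by 0.22 on chow (adjusted p = 0.356), which such sequence alone leaves unexplained. Besides these genes, none of 92 tested genes in the window of 10 megabases on either side of Nr1h3 was called for genotype on HFD, against 84 of 18810 elsewhere and 0.41 expected (one-sided Fisher's exact test, p = 1). A count of 0 allows up to 3 genes, or 3.26% of the window, against 0.447% elsewhere. The test is therefore too small to exclude such sequence, and an effect of the targeted allele on its neighbours was not tested.

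Both libraries with low Nr1h3, labelled LXRα-/- chow 4 and labelled LXRα-/- HFD 2, had Cd5l at 0.19 and 0 CPM, within the range of 0 to 1.15 of the other 8, and Ddb2 above every WT library. Overlapping gene models on the same strand, each with a mean FPKM of at least 0.5, were checked for reads that move between them. Overlaps on opposite strands were not checked. Of 406 such same-strand pairs, 7 changed more than 4-fold in opposite directions for genotype on chow, against a median of 12 and a highest of 23 over 1000 random pairings. For diet in WT 4 did, against a median of 4 and a highest of 10. Gapdh varied widely within groups, with an FPKM of 2.6 to 73.2 in WT chow, 89 to 198.9 in WT HFD, 8.7 to 223.9 in labelled LXRα-/- chow and 13 to 161.6 in labelled LXRα-/- HFD, and the reason was not tested.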
